A study of Mus musculus with 6 samples.

How the data were processed

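Kidney RNA of 6 mice was hybridised to 1-colour (Cy3) Agilent arrays of 384 rows and 164 columns of spots, 3 arrays per group. Scanner output was used for each array, and its values are spot intensities that the authors produced with Agilent Feature Extraction 10.7.3.1, per the file headers. The deposited processed signal is the intensity after background subtraction and detrending within the array, with dim spots replaced by a surrogate value, per the file headers, and it is not normalized between arrays. The flags for control, outlier, saturated and well-above-background spots were set by the same software, per the file headers. A value table of the authors was used as an alternative. Its columns are linear intensities that all have a median of 22.34, and their Spearman correlation with the processed signal of the same array was 1.0, across probes. Its scale and direction follow from that comparison, the 75th percentiles of its columns were 313.76 to 316.48, and the method that brought the medians together is not given in the sources used here. No column was left unmapped.

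Each array's log2 processed signal had its 75th percentile over spots other than controls subtracted. The percentiles were 425.06 to 459.39 before the log. Spots flagged as outliers, 102 to 178 per array, were set to missing, and spots of a probe were averaged. Probes well above background on all arrays of at least 1 group were kept, 27748 of 55681. A gene stands by its brightest kept probe, by the mean over 6 arrays, giving 20380 genes, of which 13561 have a gene symbol and the rest are lincRNA regions, models or accessions. Of the probes, 26762 (48.1%) were named through their RefSeq accession in the reference table, which updated 2878 symbols, and the others kept the name in the files. Of 476 changed genes with another kept probe, 51 had one in the opposite direction. Probe coordinates are those of the files, in mm9.

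Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, 3 arrays per group, group as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors of log2 fold changes are standard errors, those of group means are SDs, and all fold changes are D561A high salt relative to control. The labels number the mice, so arrays are separate animals. Gene lists were tested with camera at a preset correlation of 0.01, with adjustment over 34 lists of at least 3 measured genes. The lists covered chemokines, interferon responses, nephron segments, transport, metabolism, stress and other cell types, and 581 of their 588 entries are on the array. Camera with an estimated correlation and fry served as alternatives. The design, the lists, the rule for named genes and the alternatives listed below were fixed before the data were examined, while those within slide 1, without Cxcl11 and without members shared between lists were added after. The rule took the 12 largest increases and 12 largest decreases past the threshold with no overlap of the groups and a proper symbol, then Wnk4, Slc12a3, Cxcl9, Cxcl10, Cxcl11, Ccl5, Ifng, Stat1 and Ren1, and up to 4 members of each list with the smallest p.

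The alternatives were normexp background correction with an offset of 50, quantile, median and no scaling, a 75th percentile of detected probes, the authors' value table, no filter and a filter on all 6 arrays, outlier spots kept, the mean of all probes, each probe alone, trend and robust moderation, array weights, an unequal-variance test per gene, blocks for slide and for replicate number, and each array left out. Arrays lay on 2 slides scanned separately, slide 1 with 2 arrays of each group and slide 2 with 1 of each. The fits were tested on simulated data, with 67, 67 and 66 of 20376 genes changed by 0.5, 1 and 2 on the log2 scale in the comparison of D561A high salt with control. Of these, limma recovered 25.4%, 79.1% and 92.4%, with 9 false calls, and the unequal-variance test 3%, 16.4% and 43.9%. Each simulated gene had the same spread in both groups, so the simulation does not show how the tests fare with unequal spread. With 1 list shifted among 34 and genes drawn independently, camera called that list and 0 of the others. Figures were drawn with matplotlib in Python.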

Results

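Kidney RNA of 6 male C57BL/6 mice, 8 weeks old, was measured on 1-colour Agilent mouse arrays. The control group held 3 mice with both Wnk4 alleles wild type, fed 0.4% NaCl for 7 days. The other group, called D561A high salt here, held 3 mice heterozygous for the D561A substitution in the kinase WNK4, fed 8% NaCl for 7 days. Wnk4 is a regulator of the thiazide-sensitive sodium chloride cotransporter of the distal convoluted tubule. Genotype and diet changed together, so no difference below can be assigned to either of them. Each array held 59305 spots other than controls, for 55681 probes, and 48.2% to 56.8% of the probes lay well above background. No such spot was saturated, and the number of arrays limits the precision. Arrays correlated with Pearson's r of 0.991 to 0.993 within the controls, 0.994 to 0.996 within D561A high salt and 0.984 to 0.990 between the groups, across genes, which are not independent replicates.

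The question named by the series is how the kidney transcriptome of these mice differs, with a focus on chemokines that IFN-gamma induces. Of 20380 genes tested, 1332 were higher and 817 lower in D561A high salt (limma, adjusted p under 0.05, n = 3 and 3), and 368 of the higher and 170 of the lower genes changed at least 2-fold. Leaving out 1 array gave 427 to 1015 higher and 293 to 595 lower genes, the fewest of both without D561A 1. Chil3, a chitinase-like protein of myeloid cells, rose by 4.25 ± 0.24 on the log2 scale (SE, n = 3 and 3, adjusted p = 0.00114), and was well above background on 1 of 3 control arrays. The gremlins Grem1 and Grem2, secreted antagonists of bone morphogenetic proteins, were both higher. Grem1 was at least 28.7-fold higher (adjusted p = 0.00191), being not well above background on any control array, and Grem2 rose by 3.43 ± 0.35 (adjusted p = 0.00442). S100a8 and S100a9, calcium-binding proteins abundant in neutrophils, rose by 3.67 ± 0.51 and 3.49 ± 0.42. Slc6a12, a betaine transporter that responds to tonicity, rose by 2.58 ± 0.19 (adjusted p = 0.00182). The retinoic acid-binding protein gene Crabp1 rose by 3.55 ± 0.45, and Sprr2g by 3.05 ± 0.54, each on probes well above background on 1 control array. The Sprr2g call was lost without control 1 or any 1 of the D561A arrays. Stc1 was at least 6.92-fold higher, and Aunip and Kif4 were 6.25-fold and 5.97-fold higher. None of them was well above background on a control array. With normexp background correction, which shrinks differences of dim signals, Chil3 rose by 2.65, Grem1 by 1.66, Crabp1 by 1.17 and Sprr2g by 0.93 on the log2 scale. Stc1, Aunip and Kif4 rose by 0.66, 0.56 and 0.49. These values lie below the folds above, which hold for the subtracted signal alone. Of 103 named genes past the threshold, 27 differed by over 1.5 times less with normexp, 26 of which were still called, 13 lost the call with slide as a block and 38 lost it without at least 1 of the arrays.

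Among the decreases, Ces1g, a carboxylesterase, fell by 5.20 ± 0.38 on the log2 scale (SE, n = 3 and 3, adjusted p = 0.00182), from 0.91 ± 0.66 (SD) to -4.29 ± 0.49 relative to the array's 75th percentile. Slc22a7, an organic anion transporter of the proximal tubule, fell by 2.59 ± 0.40, and the cytochrome P450 gene Cyp4b1 and its pseudogene Cyp4b1-ps2 by 2.53 ± 0.30 and 3.26 ± 0.33. A gene and its pseudogene are near copies, so their probes are not independent. Serpinc1, which encodes antithrombin, fell by 2.62 ± 0.18, Slc16a14 by 2.77 ± 0.36, Pzp by 2.36 ± 0.15 and Masp2 by 2.41 ± 0.16, the last on a probe well above background on 1 of 3 D561A arrays. Dnah5, Cd209a, Serpind1 and Speer5-ps1 were not well above background on any D561A array. Dnah5 and Speer5-ps1 were at least 12.3-fold and 6.02-fold lower, and Cd209a and Serpind1 were 8.36-fold and 8.02-fold lower. The Speer5-ps1 call was lost without any 1 of the controls or without D561A 3. An "at least" fold sets the brighter group's mean against the higher, per array, of the probe's own value and the lowest signal of any probe well above background. That floor is the dimmest such probe of each array, so these folds hold for the subtracted signal and set no limit on the RNA. With normexp the log2 differences were smaller, -0.93 for Dnah5, -1.07 for Cd209a, -0.80 for Serpind1, -0.80 for Speer5-ps1 and -0.93 for Masp2. Of all changed genes 62% were higher, and this share was 49.5% with scaling to the median and 72.4% with no scaling. The arrays lay on 2 slides that each held both groups. With slide as a block, 960 genes were higher and 574 lower, and within the slide that held 2 arrays of each group, 115 were higher and 55 lower. The other slide held 1 array of each group and gives no test.

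Wnk4 itself was higher in D561A high salt by 0.44 ± 0.09 on the log2 scale (SE, n = 3 and 3, adjusted p = 0.0361), from 2.46 ± 0.06 (SD) to 2.90 ± 0.14. Its probe lies at chromosome 11, 101138198 to 101138364 in mm9, the build named in the file headers, and gives the level of the RNA, not its sequence, so it is no check of the genotype. With slide as a block the adjusted p for Wnk4 was 0.0602, and the difference was 0.54 within slide 1 and 0.24 between the pair of arrays on slide 2. The Wnk4 call was also lost with median scaling and without any 1 of the 6 arrays, with adjusted p from 0.01 to 0.192 over 23 alternatives. Slc12a3, the thiazide-sensitive cotransporter (chromosome 8, 96875636 to 96875695), rose by 0.55 ± 0.08 (adjusted p = 0.0135), by 0.54 within slide 1 and 0.55 on slide 2, and lost the call with median scaling (adjusted p = 0.0859), without D561A 1 (0.0574), without D561A 3 (0.0508), without the filter on dim probes (0.0890) and within slide 1 (0.149), with adjusted p from 0.00243 to 0.149 over 23 alternatives. Of the 19 measured genes of the list for WNK kinases and the distal convoluted tubule, 6 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone. Pvalb, a marker of the early distal convoluted tubule, rose by 1.08 ± 0.11, and the magnesium channel gene Trpm6 by 0.90 ± 0.13. Egf, made by the same segment, fell by 0.60 ± 0.08. The list's mean log2 fold change was 0.24 (camera adjusted p = 0.0367 with a preset correlation, adjusted p = 0.407 with an estimated correlation), 0.25 within slide 1 and 0.21 on slide 2, and its call was lost with quantile normalization (adjusted p = 0.0533) and without control 2 (adjusted p = 0.0807).

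**Figure D1:**
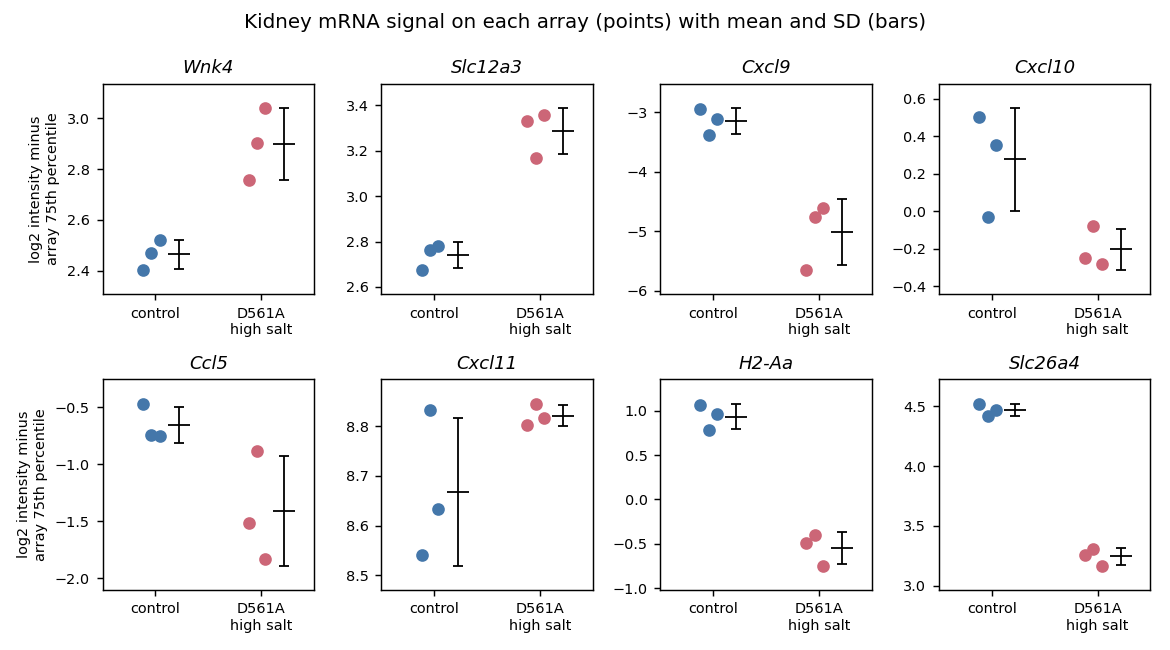
Log2 intensity relative to each array's 75th percentile (vertical axes, with a scale of their own in each panel) of 8 genes on the 3 control and 3 D561A high salt arrays, with the mean and SD as bars. The D561A values of Slc26a4 and H2-Aa lie below all control values, those of Slc12a3 and Wnk4 above them, and those of Cxcl11 overlap the control range.

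The series' own focus is the IFN-gamma-inducible chemokines, which attract T cells through the receptors CXCR3 and CCR5. A list the study chose on these samples is not independent evidence of its direction. Of the 4 members measured, Cxcl9 fell, by 1.86 ± 0.28 on the log2 scale (SE, n = 3 and 3, adjusted p = 0.0131), on its brighter probe at chromosome 5, 92752796 to 92752855. That probe was well above background on 1 of 3 D561A arrays. The other Cxcl9 probe was well above background on all control arrays and on no D561A array. By the subtracted signal it was at least 16.8-fold lower, a fold that rests on each array's dimmest probe well above background. It was not computed with normexp. With normexp background correction the Cxcl9 difference was -0.60, and the call was lost without the filter on dim probes (adjusted p = 0.0837) and within slide 1 (adjusted p = 0.0520), over a range of 0.00154 to 0.183. Cxcl10 differed by -0.48 ± 0.15 (adjusted p = 0.0905), Ccl5 by -0.75 ± 0.24 (adjusted p = 0.0950) and Cxcl11 by 0.15 ± 0.09 (adjusted p = 0.323). The Cxcl11 probe used had a control mean of 8.67, at percentile 99.9 of the mean signal of all probes. The other Cxcl11 probe had a control mean of 2.68, at percentile 89.8, and differed by 0.20 ± 0.14. Whether so bright a probe measures Cxcl11 RNA was not tested. Adjusted over the list alone, 3 members fell and none rose. The list's mean log2 fold change was -0.73 (camera adjusted p = 0.0610, and adjusted p = 0.407 with an estimated correlation), so the list as a set did not pass. Within slide 1 the mean was -0.64 and the list passed (adjusted p = 0.0431), and between the arrays of slide 2 the mean was -0.93. With slide as a block the adjusted p was 0.0539. The list passed in 9 of 22 alternatives, and its shift relative to other genes was -0.37 with normexp, against -0.77. With probes well above background on all 6 arrays alone, which leaves out Cxcl9, the shift was -0.38 and did not pass (camera adjusted p = 0.312). Without Cxcl11, an alternative chosen after the data were seen, the list passed (adjusted p = 0.00946, with 0.00946 to 0.407 over 22 alternatives). Ifng was not well above background on any array and Stat1 on only 2 arrays of each group, so neither was tested.

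Other genes that IFN-gamma induces also fell. Of 39 measured members of the IFN-gamma response list, 10 fell and none rose. Among them were the MHC class II genes H2-Aa, by 1.48 ± 0.12 on the log2 scale (SE, n = 3 and 3, adjusted p = 0.00231), and H2-Eb1, by 1.48 ± 0.17, as well as Cd74, their invariant chain, by 1.39 ± 0.18. Ubd, a ubiquitin-like modifier, fell by 2.10 ± 0.26 and was well above background on 2 of 3 D561A arrays, with -1.02 under normexp. Adjusted over the list alone, 14 fell and 2 rose. The list's mean was -0.43 (camera adjusted p = 1.27e-05, adjusted p = 0.407 with an estimated correlation), -0.44 within slide 1 and -0.39 on slide 2. In the type I interferon list 5 of 26 fell and none rose, or 10 fell and 2 rose when adjusted over the list alone, among them Irf9 by 0.44 ± 0.08 and Ifit1 by 0.86 ± 0.19 (list mean -0.25, adjusted p = 0.00325, adjusted p = 0.527 with an estimated correlation), with -0.19 within slide 1 and -0.35 on slide 2. The shift of this list relative to other genes was -0.19 without control 3, against -0.29, and by fry its adjusted p was 0.145. Irf9 and Ifit1 were each called in 13 of 23 alternatives, and Ifit1 had -0.50 with normexp. Of 10 receptor and JAK-STAT genes, Socs3, a feedback inhibitor of cytokine signalling, rose by 1.00 ± 0.15, and Socs1, Ifngr1 and Ifngr2 did not pass. Red cell RNA, described with the leukocytes, was lower in the same arrays.

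Markers of leukocytes moved in different directions. Of 11 T and NK cell genes, 5 fell and 1 rose, or 6 and 1 when adjusted over the list alone (list mean -0.65, adjusted p = 0.00140, adjusted p = 0.219 with an estimated correlation), with -0.67 within slide 1 and -0.60 on slide 2. Cxcr3 fell by 1.55 ± 0.15, Cd2 by 1.94 ± 0.24 and Thy1 by 0.86 ± 0.15. The Thy1 call was lost without any 1 of the controls or without D561A 3. Cd3d, not well above background on any D561A array, was 3.54-fold lower. Its call was lost with slide as a block (adjusted p = 0.0605, with 0.0101 to 0.192 over 22 alternatives) and without any 1 of the 6 arrays. With normexp the differences were -0.59 for Cxcr3, -0.58 for Cd2, -0.57 for Thy1 and -0.58 for Cd3d, and the shift of the list was -0.28. Cxcr3 and Cd2 were well above background on 2 and 1 of 3 D561A arrays. With probes well above background on all 6 arrays alone, the shift of the list relative to other genes was -0.25, against -0.69, and did not pass (adjusted p = 0.0920). Brighter members, named after their values were seen, did not pass either, with Cd3e at -0.13 ± 0.09 and Cd4 at -0.15 ± 0.11. In the macrophage and dendritic cell list, 1 gene of 18 rose (Lyz2, by 0.67 ± 0.16) and 1 fell (Fcgr3, by 0.74 ± 0.15), and the list did not pass (adjusted p = 0.303), but it passed, lower, within slide 1 (adjusted p = 0.0228), with a mean of -0.18 there and 0.07 on slide 2. Both genes lost the call with slide as a block (adjusted p = 0.0697 for Lyz2 and adjusted p = 0.0539 for Fcgr3, with 0.0125 to 0.227 over their alternatives). The B and plasma cell list had no changed gene among 6, with a mean of -0.01 (adjusted p = 0.892). Of 7 neutrophil genes 4 rose, including Retnlg by 1.73 ± 0.26 on a probe well above background on 1 of 3 control arrays (0.52 with normexp), and Ly6g fell by 0.68 ± 0.12, and the list did not pass (adjusted p = 0.0579), but it passed with slide as a block (adjusted p = 0.0292) and within slide 1 (adjusted p = 0.0212). Red cell RNA was lower, with a list mean of -2.40 over 7 genes (adjusted p = 0.00140, adjusted p = 0.407 with an estimated correlation), -2.34 within slide 1 and -2.52 on slide 2, while none of the 7 passed over all genes, Hbb-bs having -2.83 ± 0.88, and all 7 fell when adjusted over the list alone. Without D561A 3 the shift of this list was -1.60, against -2.44, and by fry its adjusted p was 0.0775. The correlation that camera estimated between its members was 0.618, so they are not independent. By array, the list mean was 2.74 in control 1 and 2.63 in D561A 2.

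Markers of the nephron segments beyond the distal convoluted tubule split. Of 20 genes of the connecting tubule and principal cells, 7 rose and 2 fell, or 10 and 2 when adjusted over the list alone. Calb1, a calcium-binding protein, rose by 1.54 ± 0.10 on the log2 scale (SE, n = 3 and 3, adjusted p = 0.00168), the calcium channel gene Trpv5 by 1.08 ± 0.16 and Scnn1b, a subunit of the epithelial sodium channel, by 0.60 ± 0.09. The list's mean was 0.40 (adjusted p = 0.000264, adjusted p = 0.263 with an estimated correlation), 0.44 within slide 1 and 0.34 on slide 2. Of 17 intercalated cell genes 8 fell and none rose, with 10 falling when adjusted over the list alone. Slc26a4, the chloride-bicarbonate exchanger pendrin, fell by 1.23 ± 0.07 (adjusted p = 0.00134), and Foxi1, a transcription factor of these cells, by 1.00 ± 0.15. That list's mean was -0.39 (adjusted p = 1.20e-05, adjusted p = 0.219 with an estimated correlation), -0.42 within slide 1 and -0.34 on slide 2. Of 24 proximal tubule genes 6 fell and none rose, with 8 falling when adjusted over the list alone, including Slc7a13 by 1.56 ± 0.23 and Slc13a1 by 1.28 ± 0.14 (mean -0.38, adjusted p = 0.000635, adjusted p = 0.407 with an estimated correlation), with -0.39 within slide 1 and -0.36 on slide 2. In the list of male-biased kidney genes, 5 of 11 fell, and 7 when adjusted over the list alone, among them Acsm3 by 1.86 ± 0.28 and Cyp4a12a by 1.70 ± 0.19 (mean -0.96, adjusted p = 0.000635, adjusted p = 0.407 with an estimated correlation), with -0.91 within slide 1 and -1.05 on slide 2.

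**Figure D2:**
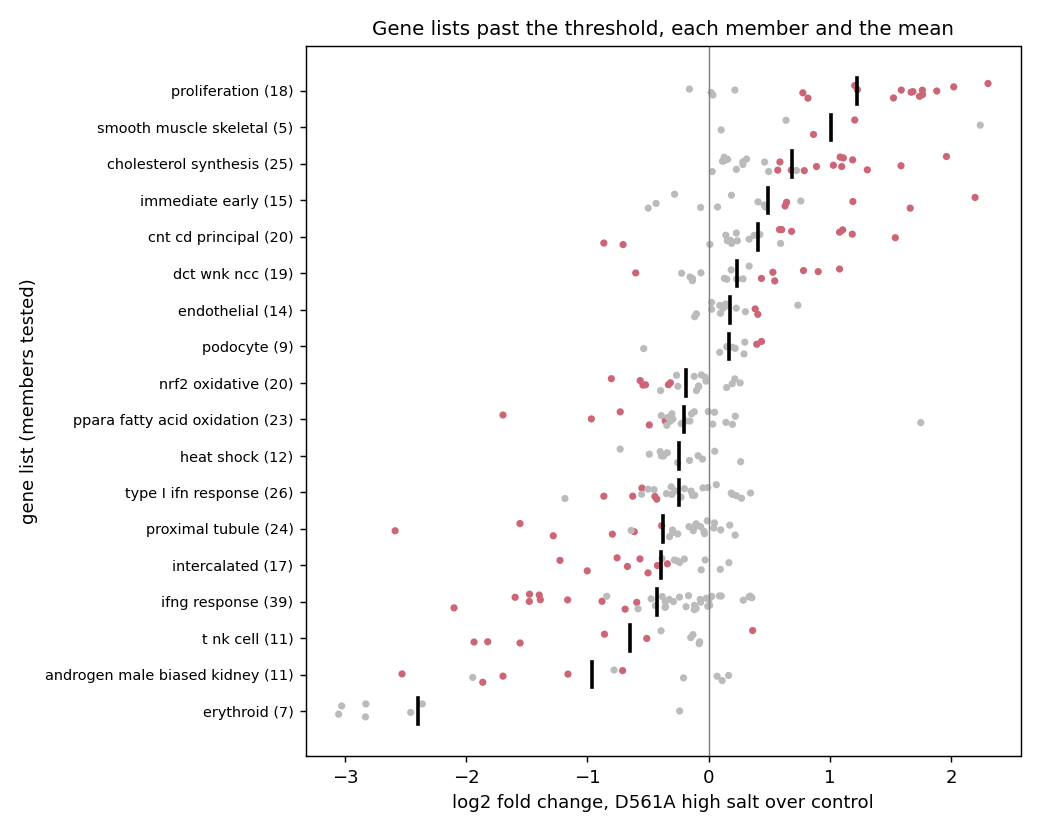
Log2 fold change of D561A high salt over control (horizontal axis) of every measured member of the 18 gene lists past the threshold with a preset correlation, ordered by their means (black bars), with members past the threshold in red and the others in grey. The cell cycle list has the highest mean, 1.23, and the red cell list the lowest, -2.40, with no member past the threshold over all genes.

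Cell cycle and cholesterol synthesis genes rose in a wide share of their lists. Of 18 cell cycle genes 14 rose and none fell, and also 14 when adjusted over the list alone. Mki67, a marker of cycling cells, rose by 1.74 ± 0.10 on the log2 scale (SE, n = 3 and 3, adjusted p = 0.00114), the cyclin gene Ccna2 by 1.53 ± 0.08 and the mitotic kinase gene Plk1 by 1.77 ± 0.11. Bub1, a spindle checkpoint kinase gene, rose by 2.02 ± 0.10 on a probe well above background on 1 of 3 control arrays. The list's mean was 1.23 (adjusted p = 2.14e-12, adjusted p = 0.102 with an estimated correlation), 1.29 within slide 1 and 1.10 on slide 2. Of 25 cholesterol synthesis genes, targets of the transcription factor SREBP2, 13 rose and none fell. Pcsk9, which drives degradation of the LDL receptor, rose by 1.96 ± 0.10, Fdft1, the squalene synthase gene, by 1.31 ± 0.10 and Nsdhl by 1.19 ± 0.07. Adjusted over the list alone, 19 rose. The mean was 0.69 (adjusted p = 9.33e-13, adjusted p = 0.102 with an estimated correlation), 0.70 within slide 1 and 0.66 on slide 2. Of 15 immediate early genes 5 rose, and 9 when adjusted over the list alone, including Fos by 2.20 ± 0.29 and Gadd45b by 1.19 ± 0.12 (mean 0.49, adjusted p = 0.00574, adjusted p = 0.263 with an estimated correlation), with 0.56 within slide 1 and 0.37 on slide 2. With normexp Fos rose by 0.50 and Bub1 by 0.44, and the shift of the immediate early list was 0.23, against 0.45.

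In all, 18 of 34 lists passed with the preset correlation, 8 higher and 10 lower, and none passed with an estimated correlation (limma camera, smallest adjusted p = 0.102, with 6 lists at an unadjusted value under 0.05). By fry, which tests whether a list's genes move one way on balance and compares them with no other genes, 18 passed, 14 of them among the 18 above. The calls of the type I interferon (adjusted p = 0.145), PPAR-alpha (adjusted p = 0.108), heat shock (adjusted p = 0.108) and red cell lists (adjusted p = 0.0775) were not shared. With slide as a block 21 lists passed, the 18 and those of neutrophils, matrix and adipose tissue, and within slide 1 22 passed, the 18 without that of podocytes, and those of the chemokines, neutrophils, matrix, injury and macrophages.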

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

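Alternatives within one slide, without Cxcl11 and without shared list members were chosen after the data were seen. Of the 103 named genes and 18 lists that passed, none changed direction under any alternative run, but 1 kept its call under all of them, the cholesterol synthesis gene Nsdhl. The unequal-variance test called 1 gene higher and 0 lower, the one at least 2-fold, while 4215 genes had an unadjusted p under 0.05 by its approximation. In simulation with equal spread in both groups it also recovered far fewer changed genes than limma at this number of arrays. That simulation cannot tell how much of the loss of calls here comes from unequal spread. Without the filter on dim probes, 139 genes were higher, 91 lower and 183 changed at least 2-fold, over 35080 genes tested. With median scaling 652 were higher. With normexp, which shrinks dim signals, 244 changed at least 2-fold. Within slide 1, with 2 arrays per group, 115 were higher, 55 lower and 170 changed at least 2-fold. Leaving out each array in turn gave 427 to 1015 higher genes, 293 to 595 lower and 342 to 529 changed at least 2-fold. The higher count moved by over 1.5 times without control 1 (692), control 3 (680), D561A 1 (427), D561A 2 (693) and D561A 3 (472), and the lower count without control 1 (362), control 2 (451), control 3 (362), D561A 1 (293) and D561A 3 (315). Fewer arrays were then tested. For the other changes of counts the cause was not tested. With an estimated correlation 0 lists passed, with 6 at an unadjusted p under 0.05 by camera and 18 past the threshold by fry.

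Replicate numbers are shared by the groups, but arrays with the same number did not deviate together (correlations of 0.022, 0.021 and -0.116). These values give no sign that the numbers pair the mice, but so few cannot exclude it. With the number as a block, 731 genes were higher and 393 lower.

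The shift of the chemokine list relative to other genes was -0.77 in the main setting and lay between -1.08 and -0.37 over 22 alternatives tested by camera, with adjusted p from 0.00946 to 0.407. It passed in 9, with -0.775 under median scaling and no scaling, -0.798 with the authors' value table, -0.731 without the filter, -1.08 with the mean of all probes, -0.682 within slide 1 and -1.07 without Cxcl11. Fry, which tests the list against no change (adjusted p = 0.0241), is not counted among these. With the filter on all 6 arrays, which leaves out Cxcl9, the shift was -0.377 and did not pass (adjusted p = 0.312). Arrays left out gave -0.882 to -0.677. The cause was not tested. Wnk4 was called in 11 of 23 alternatives, with log2 fold changes of 0.35 to 0.54 and adjusted p of 0.01 to 0.192.

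Among the named genes and the lists, values that changed sign belonged to those that had not passed. Of all 2149 changed genes, 1 changed sign with the filter on all 6 arrays and 2 with the mean of all probes. The JAK-STAT list shift was -0.00589 in the main setting and 0.0138 with normexp, 0.0159 with quantile normalization, 0.0130 with the value table, 0.0377 without the filter, 0.0168 with the filter on all arrays and 0.0340 without shared members, and -0.0414 to 0.0202 with an array left out. For renin-angiotensin the values were 0.0194, 0.00680 and 0.00963 under the first 3 of these, 0.0397 without the filter, 0.0175 with the mean of all probes and 0.00577 without shared members, and -0.0514 to 0.0366 with an array left out. The unfolded protein list gave 0.0222 without the filter, 0.00127 with the filter on all arrays and 0.0203 within slide 1, and -0.0673 to 0.00633 with an array left out. The B cell list gave 0.00192 with normexp and 0.103 without shared members. Other chemokines ranged from -0.176 to 0.0198 with an array left out. The adipose list gave 1.10 within slide 1 and -2.37 to 0.338 with an array left out. Single genes were Nr5a1 (0.0382 with no scaling, 0.0635 with array weights, -0.0921 to 0.0841 with an array left out), Mzb1 (-0.37 with the value table), Fabp4 (0.29 within slide 1, -1.12 to 0.19), Cidec (1.40 within slide 1, -3.05 to 0.45), Akr1b7 (-0.25 to 0.16) and Ccl12 (-0.0548 to 0.419). The cause was not tested. Signal over background limits all values of genes near the floor.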

Other observations

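Tests of the leukocyte and female-biased lists were written before their results were seen, and all other tests below after. Several lists that the comparison has not yet described also moved. In the smooth muscle list 2 of 5 genes rose, and 3 when adjusted over the list alone (mean 1.01, 1.30 within slide 1 and 0.43 on slide 2, adjusted p = 0.0184, adjusted p = 0.263 with an estimated correlation), with Cnn1 at 1.21 ± 0.20 and Myh11 at 0.87 ± 0.14 (SE, n = 3 and 3). With normexp the shift of this list was 0.50, against 0.97. In the endothelial and podocyte lists 2 of 14 and 2 of 9 genes rose, or 4 and 3 when adjusted over the list alone, with 1 podocyte gene falling (means 0.18 and 0.17, adjusted p = 0.0436 and adjusted p = 0.0415, with adjusted p = 0.420 and adjusted p = 0.471 with an estimated correlation), both lost with median scaling, the endothelial call also without control 1 (adjusted p = 0.0746), control 2 (0.128) or D561A 3 (0.103), and the podocyte call without control 2 (0.0549), control 3 (0.130) or D561A 2 (0.0890) and within slide 1 (0.0716), with 9 of its 22 alternatives not passing. Of 20 NRF2 targets 6 fell, and 7 when adjusted over the list alone, led by Nqo1 at -0.80 ± 0.08 (list mean -0.18, adjusted p = 0.00325, adjusted p = 0.407 with an estimated correlation). Of 23 PPAR-alpha targets 5 fell and none rose, or 6 and 1 when adjusted over the list alone, with Ehhadh at -0.97 ± 0.14 (mean -0.20, adjusted p = 0.00325, adjusted p = 0.491 with an estimated correlation), a call lost without control 1 (adjusted p = 0.0660). With an array left out the shift of this list was -0.306 to -0.137, against -0.243. The heat shock list had a mean of -0.25 (adjusted p = 0.00737, adjusted p = 0.422 with an estimated correlation) with no member past the threshold, also when adjusted over the list alone.

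Lists that did not pass still held changed genes. In the injury list Lcn2, C3 and Spp1 rose by 1.60 ± 0.17, 1.76 ± 0.34 and 1.03 ± 0.14, and Il34 fell by 1.26 ± 0.09 (list adjusted p = 0.200, but adjusted p = 0.0462 within slide 1). The C3 call was kept in 16 of 23 alternatives. In the tonicity list Slc6a6, a taurine transporter, rose by 0.68 ± 0.07 beside Slc6a12 (adjusted p = 0.138). Among matrix genes Acta2 rose by 1.08 ± 0.11 (adjusted p = 0.0752, but adjusted p = 0.0346 with slide as a block and 0.0431 within slide 1). In the renin-angiotensin list Ace2 and Agt rose by 0.96 ± 0.12 and 0.55 ± 0.10, and Ace fell by 0.60 ± 0.13 (adjusted p = 0.892), while Ren1 had -0.39 ± 0.21 (adjusted p = 0.279). Pcx fell by 0.36 ± 0.08 among genes of ammonia and glucose production (adjusted p = 0.228), Cxcl14 by 0.93 ± 0.21 among other chemokines (adjusted p = 0.892), and Chac1 rose by 1.08 ± 0.25 in the unfolded protein list (adjusted p = 0.505). With slide as a block the calls of Ace (adjusted p = 0.0660), Pcx (adjusted p = 0.0686) and Chac1 (adjusted p = 0.0737) were lost, with 0.0110 to 0.274 over their alternatives, and those of Agt and Cxcl14 were kept in 14 of 23. Lpl fell by 1.33 ± 0.15 in the adipose list (adjusted p = 0.0678, but adjusted p = 0.0405 with slide as a block), whose mean was 1.14 within slide 1 and -5.23 on slide 2. JAK-STAT genes (adjusted p = 0.586), adrenal genes (adjusted p = 0.792) and reference genes (adjusted p = 0.892) did not pass. The mean was above 0 and the median below in the JAK-STAT and unfolded protein lists, which camera placed lower, and in the renin-angiotensin list, placed higher. The reverse held for other chemokines and reference genes, placed lower, and for B cell genes, placed higher.

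In the IFN-gamma response list 10 of 39 genes fell, and in the T and NK cell list 5 of 11 fell and 1 rose, with neither list past the threshold with an estimated correlation (adjusted p = 0.407 and adjusted p = 0.219) and the second not on probes well above background on all 6 arrays. Fewer leukocytes of every kind had been foreseen to give a list of 11 genes of all leukocytes a mean log2 fold change of -0.5 or lower. The 9 measured had -0.0745 ± 0.119 (SE over arrays), which argues against a fall of that size. The 8 T and NK cell genes well above background on all arrays had -0.228 ± 0.0969. So small a fall of all leukocytes is not excluded. More blood or lymphoid tissue in the control pieces stays open, since red cell RNA was lower in D561A high salt (-2.40 ± 1.03), although among members well above background on all arrays 6 B cell genes lay above 8 T and NK cell genes by 0.222 ± 0.107. Each slide held the groups in equal number, so an offset between slides could not by itself give this fall. Within slide 1 the IFN-gamma response list had -0.445 ± 0.11. A change in interferon signalling or in T cells with genotype or diet stays open and was not tested, and it may concern few cells.

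Principal cell and intercalated cell genes moved apart, while part of the proximal tubule list fell. A larger share of medulla would lower glomerular and early proximal genes. The podocyte list had 0.172 ± 0.0606 and 6 early proximal markers a mean of 0.000151 ± 0.0628, so neither mean fell. No list of medulla genes was tested, and a rise in the share of medulla too small to lower these means is not excluded. A lower share of proximal tubule would lower those early proximal markers and raise other segments alike. The principal cell list exceeded the intercalated list by 0.797 ± 0.0728, but that difference is the pattern itself and no separate test. A change within distal segments stays a hypothesis that was not tested, with genotype and diet both open.

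Clock genes also differed. Ciart rose by 2.95 ± 0.39, on a probe well above background on 1 of 3 control arrays (0.90 with normexp). Cry2, Tef and Nr1d2 were higher but called in 15, 10 and 8 of 23 alternatives, Cry2 not without control 1 or any 1 of the D561A arrays, Tef not without any 1 of the 6 arrays and Nr1d2 not with slide as a block (adjusted p = 0.0732, with 0.0152 to 0.272 over its alternatives). Of 16 clock genes measured, 4 rose and none fell, or 9 and 4 when adjusted over the list alone. The list did not pass (camera adjusted p = 0.138, and fry adjusted p = 0.00124). Its members moved in both directions, which weakens a test of a common shift. A contrast of 8 evening-arm minus 4 opposite-arm genes separated the groups by a gap of 0.908. The hour of tissue collection may therefore have differed, which cannot be told apart from the groups. Cholesterol genes followed this contrast within groups, yet with it as a covariate their mean was 0.559 ± 0.0193 against 0.69 ± 0.0338 without, which argues against a linear trend as the whole cause. An effect of the hour in another form stays open.

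Hypotheses outside these patterns were tested too. Lower androgen response predicts higher female-biased genes, and Slc7a12, Prlr and Abcc3 had a mean of 0.345 ± 0.289. The bound set beforehand, above 0.3 by more than the error, was not met, and with Abcc3 at 0.91 ± 0.21 and Prlr at -0.18 ± 0.43 the list does not decide. Variants carried along with the Wnk4 knock-in predict more changed genes nearby. Within 10 Mb, 42 of 370 genes (11.4%) had changed against 10.5% elsewhere, a ratio of 1.08 (Fisher's exact test, two-sided, p = 0.608, genes not being independent), so no such excess was seen.

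Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. Only 1 of them, the real one, gave as many higher genes (1332, with 0 in the highest other), lower genes (817 and 0), genes changed at least 2-fold (538 and 0), lists past the threshold (18 and 15) or as large a chemokine list shift (0.775 and 0.480). At an unadjusted p under 0.05 by limma, not by an exact test, the other splits had 282 to 1119 genes against 5932. Although they called no gene, 0 to 15 lists passed in them by camera at the preset correlation, so list calls also arise in mixed groups. Each other split still sets 2 arrays of one real group with 1 of the other, so it keeps part of the real difference. The mixing also adds the real difference to the spread within its groups, which lowers its calls. The gene counts of 0 were therefore partly set by the design.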
